A study of Mus musculus with 12 samples.

How the data were processed

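Total RNA from the livers of 12 mouse samples was measured by RNA sequencing, with 4 samples on a normal diet (ND), 4 on a high-fat diet with vehicle (HFD) and 4 on a high-fat diet with MEC1 (HFD+MEC1). Per the labels' protocols, liver was flash frozen and RNA was taken with Trizol. Groups and replicate numbers came from the sample titles. The labels give no batch, sex, age or dosing period, and they do not state that each sample came from a different mouse or that equal numbers pair the samples. P-values therefore measure only the spread between these samples. That spread exceeds counting error, with a chi-square per gene of at least 35.3 between replicates of a group, but it may be technical in part.

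The authors deposited 1 table of whole-number read counts per gene symbol for each sample and 1 table of RPKM values for all samples, per the file headers. STAR 2.7.10a and the mm10 genome build are named in the submitters' processing notes, which give neither roles nor settings as used here. The tool that counted reads, its annotation, its use of strand and any filter are not stated in the sources used here. The deposited counts were not normalised: their totals ran from 39916405 to 51340317 per library. Among genes with 1 to 20 counts, 70.1 to 74.7% of the deposited counts were even in each library, so the counts look like read ends rather than read pairs, and counting error is larger than the totals alone would give. Between 244 and 296 genes per library had 0 counts and an RPKM above 0, so the deposited count and RPKM tables were not made from exactly the same reads. The RPKM table also held 12 columns that match no sample in the labels; these were not analysed here.

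Gene symbols were matched to GENCODE M21, whose assembly is the one that mm10 names: 24255 of 24787 symbols matched directly, 138 through a synonym and 394 not at all. Coordinates in the text are from that annotation and are 1-based. Because strand use is not stated, a gene whose exons overlap a gene on the opposite strand cannot be separated from it, and members of the Cyp2b, Cyp2c, Cyp3a and Cyp4a families are similar enough that reads may have been shared among them.

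Genes with too few counts were removed with filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 14172 genes holding 99.98% of all counts; 6542 genes had no count in any library. Libraries were scaled with TMM factors. One quasi-likelihood model with robust dispersion estimates was fitted to all 3 groups, and the 3 differences HFD minus ND, HFD+MEC1 minus HFD and HFD+MEC1 minus ND were tested with edgeR's quasi-likelihood F-test. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and an adjusted p under 0.05 was called a change, with no minimum fold. All tests were two-sided. The common biological coefficient of variation was 0.200. Levels are given as CPM, the counts scaled by TMM-adjusted library totals, and logarithms used a prior count of 2. A count of 3 corresponds to 0.0590 to 0.0770 CPM in the 12 libraries, which covers counting error only.

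A total of 40 gene lists were written from general knowledge before the data were examined; they cover lipid, glucose and xenobiotic metabolism, mitochondria, autophagy and the proteasome, stress and immune responses, clock and sex-biased genes, and cell type markers. The groups, the tests and the alternative settings were fixed then as well. Each list with at least 5 tested members was tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of each comparison, and again with an estimated correlation and with fry. The number of members past the threshold was counted over all genes tested and, separately, adjusted over the list alone. A list score per library is the median over members of log2 CPM minus the mean of the ND libraries, compared between groups by an exact permutation test, whose smallest possible p is 0.0286 for 4 libraries against 4. These permutation p-values were not adjusted over the lists or comparisons, so a list at 0.0286 is not called on that ground alone.

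To place the libraries between the diets, each was projected on the difference between ND and HFD over genes changed by diet, so that 0 is the ND mean and 1 the HFD mean. An ND or HFD library was left out of the axis when its own position was taken. Genes changed in opposite directions by diet and by MEC1 were counted beside splits of the HFD libraries and beside simulated sets, since both comparisons share the HFD libraries. The sets simulated first had no effect of diet, with 0 to 1 genes called by diet, and are not used for these genes. In their place, and after the data were seen, 20 sets were drawn in which HFD+MEC1 did not differ from HFD and genes called by diet kept their ND and HFD means, and 20 more in which every gene kept them. Diet called 577 to 648 genes in the first kind and 1551 to 1679 in the second, against 893 in the data; the measured means include the spread between libraries. For genes changed in both HFD and HFD+MEC1 against ND, comparisons that share the ND libraries, 20 sets with the diet effect and no difference between HFD+MEC1 and ND were drawn, and the ND libraries were split, also after the data were seen.

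Genes were named by a rule fixed before the data were examined. It took, for each comparison, up to 6 genes with the largest rise and 6 with the largest fall among those past the threshold, with a mean of at least 5 CPM and no overlap between the groups. It then took up to 4 members of each described list with the smallest p-values, a fixed set of genes of mitophagy and lipid metabolism, and up to 10 genes with opposite changes. Predicted genes, Rik clones, small RNA and Mup genes were left out of the first part. Where no gene passed on a side, the 6 with the smallest p-values were to be given as values. Which lists are described, and so which of the genes under the rule appear, was chosen after the values were seen, and some genes under the rule are not reported here. The 4 genes past the threshold in HFD+MEC1 minus HFD are also given for HFD+MEC1 minus ND, which was decided after their values were seen.

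The steps were tested on simulated counts drawn from the real means, library sizes and dispersions with 200 genes changed. For HFD+MEC1 minus HFD, 6 unchanged genes were called among 13971 genes tested in all. Of genes changed by 0.5 on the log2 scale 26% were recovered, and 74%, 92% and 96% of genes changed by 1, 2 and 3. For HFD minus ND the shares were 32%, 84%, 86% and 96%, with 4 unchanged genes called among 13977 tested. For HFD+MEC1 minus ND they were 16%, 78%, 86% and 90%, with 3 unchanged genes called among 13995 tested. DESeq2 called more unchanged genes in the same sets: 20 for HFD+MEC1 minus HFD, 22 for HFD minus ND and 15 for HFD+MEC1 minus ND. Genes were drawn independently, each with the same dispersion in all groups. Real replicates differed more outside ND, with a chi-square per gene of 35.3 to 56.4 in ND, 66.4 to 267 in HFD and 68.9 to 412 in HFD+MEC1. The shares for HFD+MEC1 minus HFD may therefore be too high.

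Other settings fixed in advance were DESeq2 1.42.0, limma-voom, other scaling factors, no filter and a stricter filter, fits of only the groups compared, replicate numbers as a block, a minimum fold, the deposited RPKM with a pseudocount of 0.5 or 0.1, and leaving out each library in turn. Halved counts and scaling by library totals only were added after seeing the data.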

Results

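The series set out to test MEC1, a compound known here only by its code name, in a chronic disease model; the title concerns PROTACs, molecules that bring a protein to a ubiquitin ligase, and mitophagy, the clearance of mitochondria by autophagy. Mice of the C57Bl/6 strain ate ND or HFD, and after 2 months those on HFD were randomised to vehicle or to MEC1 at 0.5 mg/kg, injected into the peritoneum every day. Liver RNA was sequenced in 12 libraries, 4 in each of 3 groups, with 39916405 to 51340317 counts per library. Of 24787 genes, 14172 had enough counts to be tested. The sources used here do not say how long dosing lasted or whether ND mice were injected, so the comparison of HFD with ND carries any effect of the injection. Levels below are CPM as mean ± SD with n = 4 per group, log2 fold changes carry their SE, and adjusted p values of genes are from edgeR.

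ND libraries separated from all others along the first principal component of all tested genes, which held 23.2% of the variance, and the other 2 groups overlapped on it. ND libraries lay from -35.7 to -27.9, HFD libraries from 13.9 to 41.2 and HFD+MEC1 libraries from -7.88 to 21.7. The second component held 18.1% of the variance and set HFD+MEC1 apart from HFD except in a pair of libraries. HFD replicate 4 lay at -7.93 and HFD+MEC1 replicate 1 at 6.72 on it, each toward the other group, and HFD+MEC1 replicate 3 was the farthest from the rest at -55.9.

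**Figure D1:**
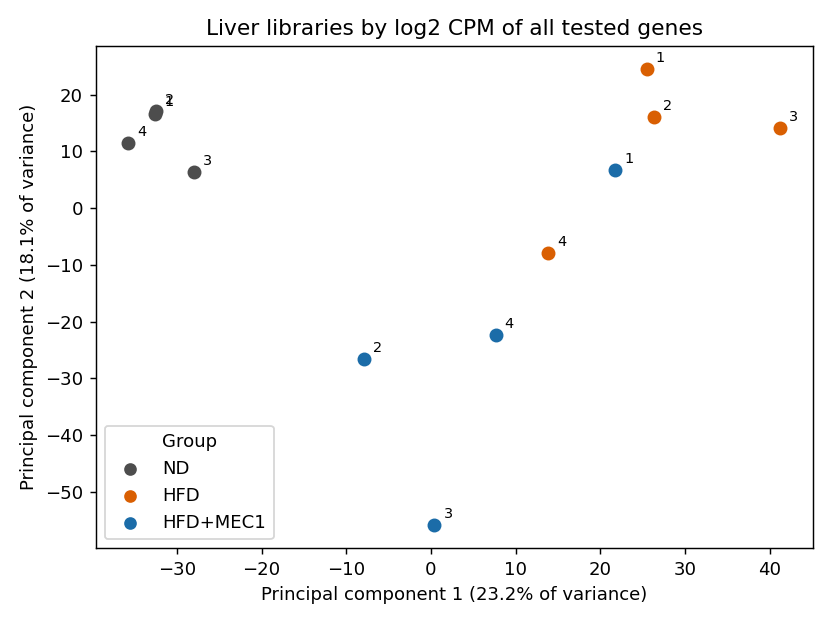
First and second principal components of log2 CPM over all tested genes, 1 point per liver library, coloured by group and numbered by replicate. ND libraries sit at the left, and HFD replicate 4 and HFD+MEC1 replicate 1 lie between the other libraries of the HFD and HFD+MEC1 groups.

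The comparison of HFD with ND asked what the diet did to the liver. Genes of fatty acid oxidation and ketogenesis were higher on HFD: 19 of 28 measured members rose, 0 fell and 9 did not pass, and adjusted over the list alone 25 rose. Their median log2 fold change was 0.72 (camera adjusted p = 1.43e-22, and adjusted p = 0.217 with an estimated correlation). Bdh1, which interconverts ketone bodies, rose from 125 ± 9.35 to 301 ± 38.8 CPM (log2 fold change 1.27 ± 0.13, adjusted p = 0.000119). Cpt1a, which controls entry of fatty acids into mitochondria (chromosome 19, 3322334 to 3385733), rose from 186 ± 19.1 to 363 ± 27.3 CPM (adjusted p = 0.000185). Cyp4a14, a fatty acid hydroxylase gene, rose from 10.4 ± 6.42 to 482 ± 262 CPM (adjusted p = 0.028), and Fgf21, a hormone made in liver, rose from 0.188 ± 0.222 to 7.01 ± 4.13 CPM (adjusted p = 0.00908). The Cyp4a14 call was lost without any 1 of the ND libraries or without HFD replicate 2 or 3, and reads of Cyp4a family members may not be separated.

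Genes of lipid storage were also higher on HFD, with 9 of 16 past the threshold, all upward, and 14 higher and 1 lower adjusted over the list alone. The median log2 fold change was 1.68 (camera adjusted p = 1.59e-10, and adjusted p = 0.217 with an estimated correlation). Cd36, a fatty acid transporter, rose from 34.0 ± 6.46 to 177 ± 78.1 CPM (log2 fold change 2.39 ± 0.38, adjusted p = 0.00671). Mogat1, an enzyme of triglyceride synthesis, rose from 0.354 ± 0.306 to 5.40 ± 2.78 CPM. The lipid droplet genes Cidec (log2 fold change 4.03 ± 0.91, adjusted p = 0.0312) and Cidea (5.77 ± 1.44, adjusted p = 0.0462) rose as well. Both calls were lost with limma-voom and without any 1 of the ND libraries or HFD replicates 2 and 3, and Cidea in HFD replicate 4 stood at 1.10 CPM against 12.5 to 16.5 CPM in the other HFD libraries. Apoa4, an apolipoprotein gene, rose by 3.73 ± 0.47, but 69.8% of its exonic sequence overlaps a gene on the opposite strand. Mfsd2a, a lipid transporter, rose from 3.79 ± 1.58 to 70.0 ± 13.2 CPM. Lipogenesis genes were not called as a list on HFD: 4 of 20 rose, 1 fell and 15 did not pass, and adjusted over the list alone 5 rose and 2 fell (median log2 fold change 0.07, camera adjusted p = 0.428). Elovl5 and Fads2, which elongate and desaturate polyunsaturated fatty acids, rose by 1.53 ± 0.20 and 1.17 ± 0.19, and Mlxipl, a glucose-responsive transcription factor, fell by 0.65 ± 0.11. Fasn stood at -0.04 ± 0.36 (adjusted p = 0.97) and Scd1 at -0.13 ± 0.37 (adjusted p = 0.886). Without HFD replicate 2 the list passed with camera.

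Xenobiotic metabolism genes were lower on HFD, with 6 of 22 members down, 0 up and 16 not past the threshold, and 8 down adjusted over the list alone. The median log2 fold change was -0.65 (camera adjusted p = 0.000103, and adjusted p = 0.384 with an estimated correlation). Ces2a, a carboxylesterase gene, fell from 377 ± 18.5 to 90.3 ± 16.4 CPM (log2 fold change -2.06 ± 0.18, adjusted p = 4.35e-05). Cyp3a11, a major drug-metabolising cytochrome (chromosome 5, 145854426 to 145879964), fell from 4106 ± 461 to 651 ± 288 CPM (adjusted p = 0.0194). Cyp3a44 and Cyp3a41a fell by 2.73 ± 0.48 and 2.60 ± 0.41 on the log2 scale, although reads of such closely related genes may not be separated. Cyp26a1, which degrades retinoic acid, fell from 65.2 ± 42.4 to 1.96 ± 0.747 CPM (adjusted p = 0.00496). Among the other genes with the largest falls, Adam11 fell by 2.83 ± 0.38 and Selenbp2 by 2.42 ± 0.61. The Selenbp2 call was lost without any 1 of the 8 libraries, and that of Cyp3a11 without HFD replicate 1 or 2.

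Among genes of stress and immune responses, 6 of 26 interferon response genes rose and 1 fell on HFD, and 10 rose and 1 fell adjusted over the list alone (median log2 fold change 0.37, camera adjusted p = 0.000367, and adjusted p = 0.275 with an estimated correlation). Ifit1 rose from 5.56 ± 0.445 to 11.1 ± 1.67 CPM (adjusted p = 0.000706). Of 19 inflammatory genes 2 rose, and 6 rose adjusted over the list alone (camera adjusted p = 0.00423, and adjusted p = 0.275 with an estimated correlation); Ccl2, a monocyte attractant, rose from 0.170 ± 0.0560 to 1.20 ± 0.311 CPM. Macrophage markers were positive in 18 of 18 members in the same comparison; 1 rose, and 2 adjusted over the list alone (median 0.28, camera adjusted p = 0.00374, and adjusted p = 0.557 with an estimated correlation). Sinusoidal endothelial markers were positive in 11 of 13, with 0 past the threshold and 3 higher adjusted over the list alone (camera adjusted p = 0.0137, and adjusted p = 0.557 with an estimated correlation), a camera call lost without ND replicate 1 or HFD replicate 4. Gdf15, a stress-induced hormone in the integrated stress response list, rose by 2.87 ± 0.41; 2 of the 18 genes of that list rose and 1 fell (3 and 1 adjusted over the list alone), with a camera adjusted p of 0.00532 and an adjusted p = 0.344 with an estimated correlation. The largest rise by fold was that of Cyp2b9, a cytochrome gene with 0 to 4 counts in each ND library and 54.8 ± 53.3 CPM on HFD (adjusted p = 0.0194). That call was lost with limma-voom and without any 1 of the ND libraries. Rgs16, a regulator of G protein signalling, rose from 0.196 ± 0.205 to 32.1 ± 21.7 CPM. The calls of Rgs16 and Fgf21 were lost with limma-voom.

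In all, 893 genes changed between HFD and ND, 475 higher and 418 lower, and 262 of them changed by at least 1 on the log2 scale. The groups did not overlap for 2022 genes, 14.3% of those tested, where chance gives 2.86% on average over groupings. The count fell to 562 without ND replicate 1, 473 without ND replicate 4 and 423 without HFD replicate 3, and was 1373 with DESeq2. With library totals in place of TMM, the median of all genes moved by 0.12 and 79.5% of called genes were higher, against 53.2% with TMM; with RPKM 71.9% were higher.

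The comparison of HFD+MEC1 with HFD was the randomised one and asked what the compound did on the diet. Only 4 genes passed with edgeR, each at an adjusted p of 0.0499 and each without overlap between the groups. Pnpla3, a lipid droplet protein gene of the lipogenesis list (chromosome 15, 84167837 to 84187236), fell from 2.14 ± 1.47 to 0.141 ± 0.0444 CPM (log2 fold change -3.91 ± 0.61), a level under the 0.739 ± 0.366 CPM of ND. Pnpla3 was rare, with 26 to 182 counts in HFD libraries, 4 to 8 in HFD+MEC1 libraries and 10 to 48 in ND libraries. Tkt, transketolase of the pentose phosphate pathway (chromosome 14, 30548359 to 30574720), fell from 118 ± 16.1 to 75.6 ± 7.73 CPM, and Hnmt, which methylates histamine (chromosome 2, 24002910 to 24049394), from 30.1 ± 4.30 to 17.4 ± 3.01 CPM. Fbxo21, a substrate-binding subunit of a ubiquitin ligase (chromosome 5, 117976730 to 118010201), rose from 44.5 ± 4.99 to 78.0 ± 6.58 CPM (log2 fold change 0.81 ± 0.12).

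Lipogenesis genes were lower as a list in HFD+MEC1 than in HFD. Of 20 members 18 had a negative log2 fold change, 1 fell past the threshold and 15 fell adjusted over the list alone, with a median of -0.84 (camera adjusted p = 1.14e-11, and adjusted p = 0.353 with an estimated correlation). The list score was 0.127 ± 0.289 in HFD and -0.731 ± 0.404 in HFD+MEC1, with no overlap (exact permutation p = 0.0286, the smallest that 4 against 4 can give). Fasn, fatty acid synthase (chromosome 11, 120805846 to 120824547), stood at 788 ± 247 CPM in HFD and 286 ± 135 CPM in HFD+MEC1 (log2 fold change -1.46 ± 0.37, adjusted p = 0.134). Scd1, the stearoyl-CoA desaturase (chromosome 19, 44394455 to 44407879), stood at 7593 ± 3558 and 2783 ± 1351 CPM (adjusted p = 0.134), and Srebf1, which encodes a transcription factor of lipogenesis, at 193 ± 29.9 and 108 ± 32.8 CPM (adjusted p = 0.101). Gpam (log2 fold change -0.86 ± 0.16, adjusted p = 0.0632) and Pklr (-1.12 ± 0.24, adjusted p = 0.101) also missed the threshold. Without HFD+MEC1 replicate 1, and with DESeq2, all 5 of these genes passed, but DESeq2 called more unchanged genes than edgeR in simulated sets.

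Lipid storage genes were lower as a list as well, with 15 of 16 members negative, 0 past the threshold, 7 lower adjusted over the list alone and a median of -0.95 (camera adjusted p = 2.28e-06, and adjusted p = 0.353 with an estimated correlation). Their list score was 1.65 ± 0.428 in HFD and 0.786 ± 0.587 in HFD+MEC1 (exact permutation p = 0.0571). Cd36 stood at 177 ± 78.1 CPM in HFD and 61.9 ± 24.6 CPM in HFD+MEC1 (adjusted p = 0.13), Fabp4 at 12.6 ± 1.93 and 7.40 ± 0.843 CPM (adjusted p = 0.0576), and Mogat1 at 5.40 ± 2.78 and 1.36 ± 0.511 CPM (adjusted p = 0.139). Cidea (log2 fold change -3.45 ± 1.19, adjusted p = 0.227) and Cidec (-2.04 ± 0.81, adjusted p = 0.288) did not pass, but did so without HFD+MEC1 replicate 1. Fatty acid oxidation genes had a median of -0.16 with 0 of 28 past the threshold, over all genes or adjusted over the list alone (camera adjusted p = 0.00476, and adjusted p = 0.701 with an estimated correlation), and the camera call was lost without HFD replicate 3 or HFD+MEC1 replicate 2. Cpt1a stood at 363 ± 27.3 and 430.2 ± 52.5 CPM (adjusted p = 0.32).

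**Figure D2:**
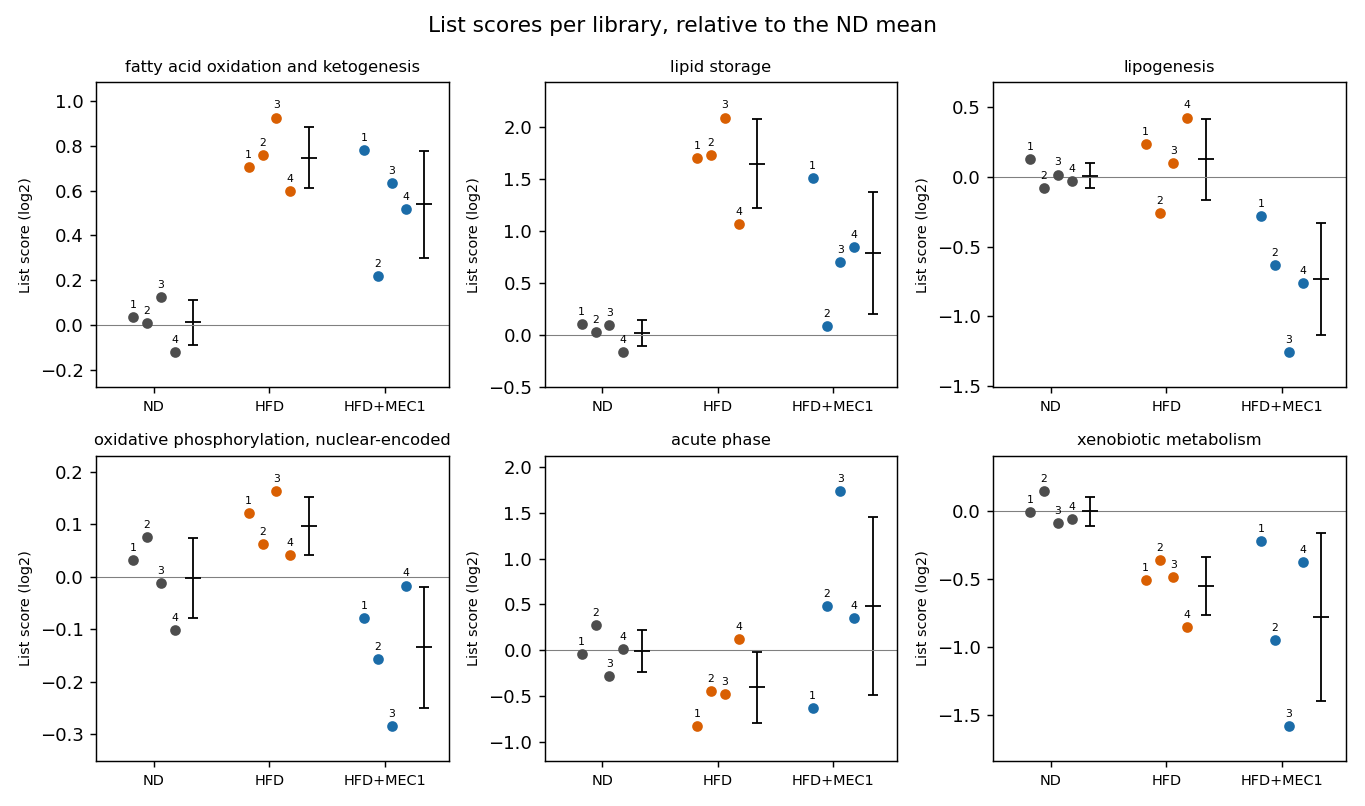
List scores of 6 gene lists, 1 point per liver library numbered by replicate, as the median over members of log2 CPM minus the ND mean, with bars for mean ± SD of 4 libraries. The lipogenesis scores of HFD+MEC1 lie from -1.26 to -0.279, all under those of HFD, which lie from -0.255 to 0.428.

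Nuclear-encoded genes of oxidative phosphorylation were slightly lower in HFD+MEC1: 76 of 77 members were negative with a median of -0.22, 0 passed singly and 20 were lower adjusted over the list alone (camera adjusted p = 6.76e-18, and adjusted p = 0.353 with an estimated correlation). The list score was 0.0971 ± 0.0554 in HFD and -0.134 ± 0.115 in HFD+MEC1 (exact permutation p = 0.0286). Ndufa6 and Ndufs4, subunits of complex I, stood at -0.33 ± 0.08 and -0.27 ± 0.07 (adjusted p = 0.101 and 0.124). Mitophagy genes, the process in the series title, were not called as a list: 0 of 34 members passed, over all genes or adjusted over the list alone, and the median was -0.05 (camera adjusted p = 0.222). Pink1, the kinase that marks damaged mitochondria, stood at 158 ± 15.4 CPM in HFD and 133 ± 8.38 CPM in HFD+MEC1 (adjusted p = 0.209). Park2, the ubiquitin ligase parkin, stood at 0.888 ± 0.482 and 0.977 ± 0.231 CPM (adjusted p = 0.913), and Usp30, a mitochondrial deubiquitinase, had a log2 fold change of -0.03 ± 0.11 (adjusted p = 0.931). Bnip3 and Sqstm1 stood at -0.29 ± 0.14 and -0.03 ± 0.12, with 27.2% and 20.5% of their exonic sequence overlapping a gene on the opposite strand. Nipsnap1 stood at -0.38 ± 0.12 (adjusted p = 0.163). Autophagy machinery, lysosome and mitochondrial biogenesis genes had medians of 0.02, 0.01 and -0.03 with 0 members past the threshold (camera adjusted p = 0.565, 0.565 and 0.456). Ppargc1a and Tfam, regulators of mitochondrial biogenesis, stood at -0.43 ± 0.21 and -0.08 ± 0.09. Of 44 genes of the proteasome and of ubiquitin ligases that PROTACs use, 0 passed and 1 was lower adjusted over the list alone (median -0.02, camera adjusted p = 0.565). Values here are mRNA levels, and mitophagy itself was not measured.

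Acute phase genes, which liver secretes in inflammation, were positive in 21 of 21 members with a median of 1.04; 0 passed and 1 rose adjusted over the list alone (camera adjusted p = 5.09e-06, and adjusted p = 0.54 with an estimated correlation). Their list score was -0.405 ± 0.391 in HFD and 0.486 ± 0.972 in HFD+MEC1 (exact permutation p = 0.114), with HFD+MEC1 replicate 3 at 1.74 and HFD+MEC1 replicate 1 at -0.634. Saa3 stood at 4.36 ± 0.380 CPM in HFD and 107 ± 193 CPM in HFD+MEC1 (adjusted p = 0.203), where replicate 3 was at 396 CPM and the others at 3.35 to 22.9 CPM. Without that library its log2 fold change moved from 4.61 to 1.31. C3 stood at 4128 ± 649 and 7726 ± 3296 CPM (adjusted p = 0.108). Endoplasmic reticulum stress genes were higher as a list, with 18 of 19 positive, 0 past the threshold, 6 higher adjusted over the list alone and a median of 0.34 (camera adjusted p = 5.09e-06, and adjusted p = 0.39 with an estimated correlation); the chaperone genes Pdia6 and Calr stood at 0.49 ± 0.15 and 0.38 ± 0.12. NRF2 targets were lower, with 0 of 18 past the threshold, 9 lower adjusted over the list alone and a median of -0.40 (camera adjusted p = 7.13e-05, and adjusted p = 0.353 with an estimated correlation). Pgd, of the pentose phosphate pathway, stood at 48.1 ± 7.73 and 28.8 ± 4.39 CPM (adjusted p = 0.0576), and Gstm1, a glutathione transferase, at 776 ± 206 and 427 ± 123 CPM. Cell cycle genes were lower, with 22 of 25 negative, 0 past the threshold, 5 lower adjusted over the list alone and a median of -0.29 (camera adjusted p = 5.09e-06, and adjusted p = 0.353 with an estimated correlation); Mki67 stood at 3.50 ± 0.923 and 1.61 ± 0.915 CPM. Of cholesterol synthesis genes, 0 of 24 passed and 5 were higher adjusted over the list alone (median 0.20, camera adjusted p = 0.00471, and adjusted p = 0.701 with an estimated correlation), a camera call lost without HFD replicate 2 or HFD+MEC1 replicate 2. Mvk stood at 22.6 ± 4.47 and 43.9 ± 8.62 CPM (adjusted p = 0.0576). Of glucose metabolism and insulin signalling genes, 0 of 18 passed, and 6 were lower and 1 higher adjusted over the list alone (median -0.31, camera adjusted p = 0.00087, and adjusted p = 0.353 with an estimated correlation). List scores gave exact permutation p values of 0.0571 for NRF2 targets, 0.314 for cholesterol synthesis and 0.0857 for glucose metabolism. The values were 0.0286 for endoplasmic reticulum stress and 0.0286 for cell cycle genes. Bile acid, integrated stress response, inflammatory and interferon response genes had camera adjusted p values of 0.845, 0.797, 0.715 and 0.261.

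Camera called 16 of 36 lists in this comparison, 0 of them with an estimated correlation, and fry called 1, the NRF2 targets (adjusted p = 0.0255). Unadjusted p was under 0.05 for 2101 genes, and DESeq2 called 378. The groups did not overlap for 1007 genes, 7.11% of those tested, where chance gives 2.86% on average over groupings. Genes vary together, so a single grouping may lie far from that average, and the excess alone does not show an effect of MEC1. The edgeR count was 0 without HFD replicate 1 or 3 or HFD+MEC1 replicate 2, 3 or 4, 7 without HFD replicate 2, 72 without HFD replicate 4 and 460 without HFD+MEC1 replicate 1. The 4 called genes were lost with a mean of at least 1 CPM, with RPKM and with library totals, and 3 of them, all but Fbxo21, with limma-voom and with only the compared groups in the fit.

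The comparison of HFD+MEC1 with ND showed where the treated livers stood against normal livers. Lipogenesis genes were below ND: 10 of 20 fell, 1 rose and 9 did not pass, and adjusted over the list alone 10 fell and 2 rose (median -0.52, camera adjusted p = 3.77e-06, and adjusted p = 0.334 with an estimated correlation). Srebf1 fell from 293 ± 35.3 CPM in ND to 108 ± 32.8 CPM (log2 fold change -1.44 ± 0.19, adjusted p = 0.00128), Acacb, an acetyl-CoA carboxylase, by 1.67 ± 0.32 and Thrsp, a lipogenic regulator, by 3.01 ± 0.62. The Acacb call was lost without HFD+MEC1 replicate 4, and that of Thrsp without ND replicate 1, 2 or 4 or HFD+MEC1 replicate 2 or 4. Fasn fell by 1.50 ± 0.37 (adjusted p = 0.0481) and Scd1 by 1.58 ± 0.38 (adjusted p = 0.0383), and both calls were lost without any 1 of the ND libraries or of HFD+MEC1 replicates 2, 3 and 4. Pnpla3 fell by 2.38 ± 0.61, a call lost without any 1 of the HFD+MEC1 libraries or of ND replicates 1, 3 and 4. Tkt fell by 0.45 ± 0.10, Fbxo21 rose by 0.58 ± 0.12, and Hnmt stood at -0.43 ± 0.13 (adjusted p = 0.0625). Without ND replicate 1 or 3, or HFD+MEC1 replicate 3 or 4, the Tkt call was lost.

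Fatty acid oxidation genes stayed above ND, with 14 of 28 higher and 0 lower, and 22 higher adjusted over the list alone (median 0.50, camera adjusted p = 2.85e-16, and adjusted p = 0.19 with an estimated correlation). Cpt1a rose by 1.21 ± 0.11 (adjusted p = 3.32e-05), Ppara, a nuclear receptor for fatty acids, by 0.85 ± 0.11 and Vnn1, its target, by 2.53 ± 0.38. Cyp4a14 rose by 4.97 ± 1.18, with 1047 CPM in HFD+MEC1 replicate 1 against 38.2 to 142 CPM in the other HFD+MEC1 libraries; that call was lost without any 1 of the ND libraries or HFD+MEC1 replicate 3 or 4. Of 16 lipid storage genes 2 rose, and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000566, and adjusted p = 0.334 with an estimated correlation); Cd36 stood at 0.87 ± 0.37 (adjusted p = 0.233), Cidea at 2.32 ± 1.49 (adjusted p = 0.453) and Cidec at 1.99 ± 0.89 (adjusted p = 0.262). Xenobiotic metabolism genes stayed below ND, with 7 of 22 lower and 0 higher, and 10 lower adjusted over the list alone (camera adjusted p = 4.83e-09, and adjusted p = 0.19 with an estimated correlation). Cyp3a11 fell to 262 ± 192 CPM (log2 fold change -3.97 ± 0.58, adjusted p = 0.00511), and Cyp3a41a, Cyp3a44 and Cyp3a59 by 3.93, 3.90 and 2.75 on the log2 scale. Cyp26a1 fell by 5.08 ± 0.74. Zbtb16, a zinc finger transcription factor, rose from 5.70 ± 0.888 to 36.7 ± 3.99 CPM (log2 fold change 2.68 ± 0.34, adjusted p = 0.00163). Rgs16, Mfsd2a and Apoa4 rose by 5.87 ± 1.31, 2.84 ± 0.63 and 2.21 ± 0.44. The calls of Rgs16 and Mfsd2a were lost without any 1 of the ND libraries or HFD+MEC1 replicate 1 or 4, and that of Apoa4 without ND replicate 1 or 4 or HFD+MEC1 replicate 3.

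In all, 644 genes changed between HFD+MEC1 and ND, 304 higher and 340 lower, and 348 of them also changed in HFD minus ND, all with the same sign. Both comparisons share the ND libraries, which alone draws their signs together. In simulated sets with the diet effect and no difference between HFD+MEC1 and ND, only 0 to 2 genes passed in HFD+MEC1 minus ND. Their overlap of 0 to 2 genes was thus fixed in advance and is no benchmark for the 348. Of genes changed in HFD minus ND, 97.5% had the same sign in HFD+MEC1 minus ND. That share was 55.4 to 62.5% in those sets and 84.2 to 97.6% with separate ND libraries. Independent lists would share 10.2 genes higher in both and 10.03 lower in both, against 176 and 172, and with separate ND libraries for each comparison 68 to 104 genes passed in both, all with the same sign. The groups did not overlap for 1554 of the 14172 tested genes, where chance gives 2.86% on average over groupings. The count was 390, 419 and 334 without ND replicates 1, 2 and 4, and 1142 with DESeq2. Of the called genes 47.2% were higher with TMM, 66.8% with library totals and 63.2% with RPKM.

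**Figure D3:**
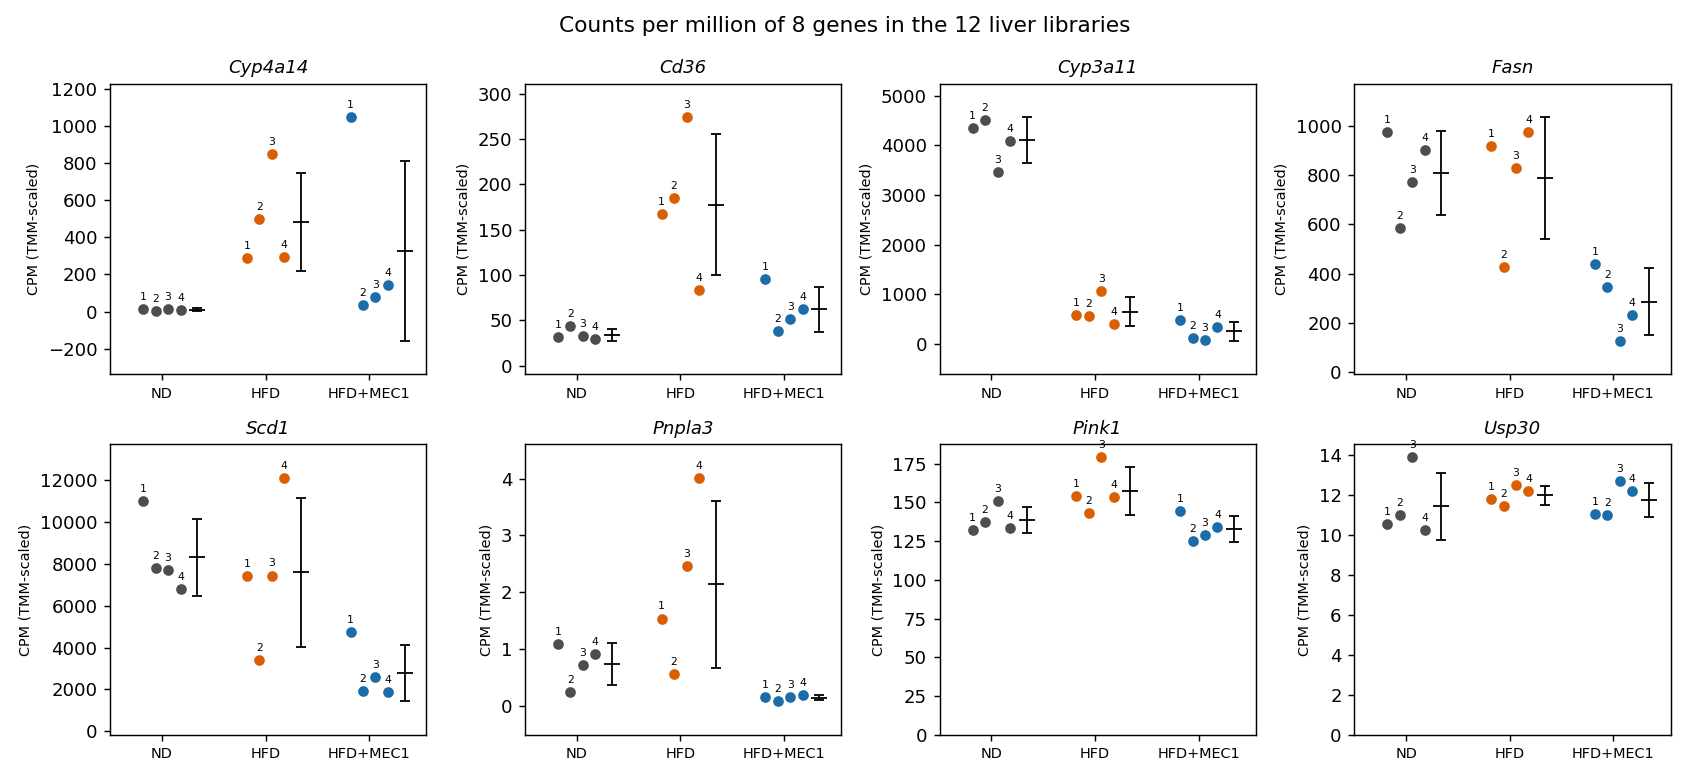
TMM-scaled CPM of 8 genes in the 12 liver libraries, 1 point per library numbered by replicate, with bars for mean ± SD of 4 libraries. Fasn and Scd1 were about level in ND and HFD and lower in most HFD+MEC1 libraries, while Pink1 and Usp30 overlapped among the 3 groups.

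Whether MEC1 moved the livers back toward ND was asked of single genes and of each library as a whole. With edgeR, 0 genes passed in opposite directions in HFD minus ND and HFD+MEC1 minus HFD, where splits of the HFD libraries gave 0 to 6; limma-voom gave 0 and DESeq2 154. Without HFD replicate 2 the count was 3, without HFD replicate 4 it was 44 and without HFD+MEC1 replicate 1 it was 164. Both comparisons share the HFD libraries, which alone sets their signs apart, so values below are given beside simulated sets that kept the diet effect of called genes and had no MEC1 effect. At an unadjusted p under 0.05 in both, 774 genes had opposite signs and 66 the same sign, against 124 to 179 and 11 to 31 in those sets, and 189 to 279 and 29 to 57 in sets where every gene kept its diet difference. Of the genes changed by diet, 81.1% had the opposite sign under MEC1, against 57.0 to 62.0% in those sets, 65.6 to 69.3% where every gene kept that difference, and 62.1 to 79.4% in the real libraries when separate HFD libraries were used for each comparison. The covariance of the log2 fold changes over genes was -0.101, against -0.0441 to -0.0366 in the sets with called genes, and it was -0.0717 to -0.0431 with separate HFD libraries, with correlations of -0.302 to -0.164. Genes were drawn independently in the simulated sets and are not independent replicates, so these ranges may be narrower than real libraries would give. On the scale from ND at 0 to HFD at 1, HFD libraries lay at 0.917 ± 0.199 and HFD+MEC1 libraries at 0.665 ± 0.142, a difference of -0.252 that did not pass (exact permutation p = 0.0857, the smallest possible being 0.0286). The difference was -0.110 without HFD replicate 3.

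Cholangiocyte markers were lower as a list in HFD+MEC1 than in HFD, with 9 of 10 negative, 0 past the threshold, over all genes or adjusted over the list alone, and a median of -0.66 (camera adjusted p = 0.0053, and adjusted p = 0.353 with an estimated correlation). Their list score was -0.206 ± 0.305 in HFD and -0.843 ± 0.173 in HFD+MEC1, with no overlap (exact permutation p = 0.0286, not adjusted over the lists). Several members were rare: Cftr held 10 to 20 counts in HFD libraries and 0 to 10 in HFD+MEC1 libraries, and Cldn7 16 to 30 and 6 to 19. Spp1, a far more abundant member, held 1276 to 2528 and 1262 to 2943 counts. Macrophage, T and NK cell, B and plasma cell, neutrophil, sinusoidal endothelial, erythroid and hepatocyte markers had 0 members past the threshold and camera adjusted p values of 0.548, 0.435, 0.715, 0.699, 0.282, 0.874 and 0.715 in the same comparison. Neutrophil markers had a median of -0.17 and a camera direction of up. Stellate cell and fibrosis genes had 0 of 25 past the threshold, over all genes or adjusted over the list alone, and a median of -0.25 (camera adjusted p = 0.0461, and adjusted p = 0.701 with an estimated correlation), a call lost without any 1 of HFD replicates 1, 2 and 3 and HFD+MEC1 replicates 3 and 4. Adipocyte, pancreatic acinar and skeletal muscle markers had 4, 3 and 1 measured members, too few for camera, with medians of 0.16, 0.15 and 0.32 and 0 past the threshold. Mesothelium and gut epithelium markers had a median of -0.53 (camera adjusted p = 0.0748), with HFD+MEC1 replicate 1 at a list score of 0.813 against -0.614 to -0.469 in the other HFD+MEC1 libraries. No symbol of the 26 names listed for genes of the mitochondrial genome was among the count tables' symbols, so these were not analysed here.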

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

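The tests of swapped labels, immune cells, library scaling and fasting were chosen, or their criteria rewritten, after the results were seen; the others were written before. Of 384 groups of 4 values, 13 (3.39%) held a library whose gap to the nearest other, as a share of the group's range, was above Dixon's critical value for 4 values, and chance gives about 1 in 20.

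HFD replicate 4 and HFD+MEC1 replicate 1 stood apart from their groups, each toward the other; Cidea in HFD had a gap of 0.895 of the range, with replicate 4 at 0.20 against 3.64 to 4.05 log2 CPM, and Atg14 in HFD one of 0.893, with replicate 4 at 4.20 against 3.76 to 3.81. On the axis from HFD to HFD+MEC1 drawn from the other 6 libraries, HFD replicate 4 lay at 0.509 and HFD+MEC1 replicate 1 at 0.331, where left-out HFD libraries lay at 0.207 to 0.298 and left-out HFD+MEC1 libraries at 0.577 to 0.880 (SD 0.114), so swapped labels cannot be told apart from livers that differed for other reasons, because HFD replicate 4 sits near the middle. Single measures go both ways. Lipogenesis scores were 0.428 in HFD replicate 4, the highest of HFD, and -0.279 in HFD+MEC1 replicate 1. The latter lay just under the lowest HFD library at -0.255, nearer to it than to the next HFD+MEC1 library at -0.630. Cell cycle scores in the same libraries were 0.653 and 0.0822, each nearer its own label. Acute phase scores were 0.122 and -0.634, each with the other group. Of genes chosen with the labels as given, Zbtb16 (15.8 and 35.3 CPM), Fbxo21 (49.1 and 82.2 CPM) and Pnpla3 (4.01 and 0.148 CPM) go with the labels. More immune cells in livers with high acute phase genes may contribute and also stay open, with a Spearman rho of 0.429 (exact permutation p = 0.299) and a Pearson r of 0.597 (exact permutation p = 0.113; 0.529 without the 2 libraries farthest from the median) over 8 libraries, the only relation of this kind computed. A difference in exposure or response among mice was not tested, since the labels give neither, and sample and dosing records would decide.

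Lipogenesis genes were lower in HFD+MEC1 than in HFD by 0.859 in list score (difference -0.859, SE 0.248). Scaling is argued against, since library totals alone gave -0.911 (SE 0.280) and moved the difference by only -0.0524 (SE 0.0549); an earlier criterion, that no HFD+MEC1 library lie above the lowest HFD library, was missed (-0.0800 against -0.1797) and was replaced after that was seen. With the acute phase score of the same livers as a covariate, the difference was -0.580 (SE 0.249), which met the criterion written before. That criterion made no allowance for so few libraries, and the slope was -0.313 (SE 0.159). The acute phase response therefore stays open as a cause. More fasted mice in the treated group might lower lipogenesis and stay open: 20 genes induced by fasting differed by -0.108 (SE 0.134, exact permutation p = 0.429), but 7 were positive and 12 are shared with the lists of fatty acid oxidation or glucose metabolism. An effect of MEC1 on lipid synthesis is a hypothesis that these livers leave open, and recorded feeding and liver triglycerides would test it.

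Oxidative phosphorylation genes were lower in HFD+MEC1 than in HFD by a small amount in nearly all members (difference -0.231, SE 0.0639). A bias from gene length or GC content is argued against as the whole cause, since the difference was -0.150 (SE 0.05005, exact permutation p = 0.0286, the smallest possible) after both trends were removed over all 77 genes. A general loss of short abundant transcripts is argued against, since 79 cytosolic ribosomal protein genes differed by 0.0519 (SE 0.0419). A lower share of all mitochondrial protein genes could account for part of it and stays open, with 76 mitochondrial ribosome genes at -0.0677 (SE 0.0337), a smaller fall. Other lists that hold mitochondrial genes went both ways. Mitochondrial biogenesis and proteostasis genes differed by -0.0172 (exact permutation p = 0.571). Fatty acid oxidation and ketogenesis genes differed by -0.208 (exact permutation p = 0.2). An effect of MEC1 on mitochondrial content is a hypothesis that mitochondrial DNA or protein levels would test.

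The other values are given without explanation. Cps1 in HFD+MEC1 had a gap of 0.859 of the range, with replicate 3 at 10.16 against 11.08 to 11.23 log2 CPM. Thrsp in HFD+MEC1 had one of 0.857, with replicate 3 at 3.47 against 5.46 to 5.79 log2 CPM, and Cyp2c55 in HFD+MEC1 one of 0.829005, with replicate 3 at -2.003 against -0.20 to 0.17. For Egr1 in HFD the gap was 0.875, with replicate 1 at 2.54 against 4.41 to 4.68 log2 CPM. For Hadhb in HFD it was 0.872, with replicate 3 at 6.73 against 6.41 to 6.45 log2 CPM. Saa3 in HFD reached 0.914, with replicate 2 at 1.94 against 2.19 to 2.21 log2 CPM. The mitophagy score in ND reached 0.857, with replicate 2 at 0.0448 against -0.0242 to -0.0143. The mitochondrial biogenesis and proteostasis score in HFD reached 0.956, with replicate 1 at 0.0574 against -0.00695 to -0.00414. For the integrated stress response score in HFD+MEC1 the gap was 0.947, with replicate 4 at 0.0821 against 0.470 to 0.492. The circadian clock score in ND had a gap of 0.846, with replicate 2 at 0.113 against -0.0576 to -0.0314. The mesothelium and gut epithelium score in HFD+MEC1 had a gap of 0.898, with replicate 1 at 0.813 against -0.614 to -0.469.

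Other splits of the same libraries tested whether the counts of changed genes could arise from any grouping. For HFD minus ND, 1 of 35 splits, the real one, gave 893 genes and the highest other gave 3. For HFD+MEC1 minus ND, 1 of 35 gave 644 and the highest other gave 1. In both, 1 of 35 is the smallest share that these splits can give. The other splits mixed the diets within a group, which widens the spread and keeps counts low. These splits therefore argue against chance but do not exclude it. For HFD+MEC1 minus HFD, 2 of 35 splits gave 4 or more genes, so chance cannot be excluded. The other was the split that exchanges HFD replicate 4 and HFD+MEC1 replicate 1, with 318 genes, which points to a structure of the samples. For opposite changes the real count was 0, which 70 of 70 labelings reach by construction, so this count says nothing about chance; the highest other was 162.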

How the results depend on the processing

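Halved counts and library totals were added after seeing the data; the other settings were fixed before. The count of changed genes in HFD minus ND was 893, with 1373 by DESeq2, 262 with a log2 change of at least 1, and 423 to 911 without single libraries; the remaining settings gave 854 to 1159. In HFD+MEC1 minus HFD it was 4, with 378 by DESeq2, 2 by limma-voom, 17 with no filter, 0 with a mean CPM of at least 1, 2 with only the compared groups, 21 with a replicate block, 1 with RPKM, 0 with library totals, 1 with a log2 change of at least 1 and 0 to 460 without single libraries; other scalings and halved counts gave 4. In HFD+MEC1 minus ND it was 644, with 1142 by DESeq2, 197 with a log2 change of at least 1 and 334 to 678 without single libraries; the remaining settings gave 517 to 716. Deviations from group means gave little sign that equal numbers pair the samples, but they cannot exclude it. Over 12 pairs they correlated at -0.0942 to 0.133, and not every sample correlated best with its own number. Opposite changes numbered 0, with 154 by DESeq2, 6 with no filter, 9 with a replicate block and 0 to 164 without single libraries, and 0 in the remaining settings. The position kept its sign, at -0.331 to -0.110 without single libraries (exact permutation p = 0.0571 to 0.257), and at -0.360 to -0.166 over splits of the HFD libraries. Lists past the threshold numbered 18, 16 and 19 in the 3 comparisons and 0, 0 and 0 with an estimated correlation; fry gave 1 and, in either direction, 10 in HFD+MEC1 minus HFD, and 8 in HFD+MEC1 minus ND.

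Of 120 named gene results, 79 passed the threshold; of these, 54 kept their call in every setting that used all libraries and 50 kept it without each library in turn; 7 changed sign in a setting, and of these none passed. Fasn in HFD minus ND was 0.0156 and 0.0153 with RPKM at either pseudocount, 0.0855 with library totals, and -0.169 to 0.167 without single libraries. Scd1 there ran from -0.449 to 0.113 and Park2 from -0.250 to 0.410. In HFD+MEC1 minus HFD, Usp30 ran from -0.0652 to 0.00227, Park2 from -0.0913 to 0.563 and Sqstm1 from -0.100 to 0.0876. Cidea in HFD+MEC1 minus ND ran from -0.217 to 2.85. The cause was not tested, except that leaving out a library or filtering also removes data, and a fold minimum only removes genes. Depth limited rare genes: 3 counts are 0.0590 to 0.0770 CPM.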

Other observations

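Periportal hepatocyte markers moved with the diet, and pericentral markers did so less clearly. Periportal markers were lower in HFD than in ND, with 6 of 13 down and 0 up, and 8 down and 1 up adjusted over the list alone (median log2 fold change -0.52, camera adjusted p = 1.45e-06, and adjusted p = 0.217 with an estimated correlation). Hal, which degrades histidine, fell from 382 ± 25.1 to 183 ± 33.1 CPM (n = 4, adjusted p = 0.000231), and Gls2, the liver glutaminase, fell by 0.84 ± 0.11. Cps1, the first enzyme of the urea cycle, fell by 1.18 ± 0.22, but it belongs to the general hepatocyte list and not to the periportal list. In HFD+MEC1 against ND, 8 of 13 periportal markers fell (9 adjusted over the list alone), Hal by 1.07 ± 0.13 and Gls2 by 1.19 ± 0.11 (camera adjusted p = 4.14e-08, and adjusted p = 0.19 with an estimated correlation). General hepatocyte markers moved with them, with 10 of 12 negative, 1 down, 3 down adjusted over the list alone and a median of -0.10 (camera adjusted p = 0.027, and adjusted p = 0.388 with an estimated correlation), a camera call lost without ND replicate 2 or 3 or HFD+MEC1 replicate 2 or 3. The general hepatocyte list score was 0.000971 ± 0.0726 in ND and -0.162 ± 0.129 in HFD+MEC1 (exact permutation p = 0.0857). Of 14 pericentral markers 3 rose in HFD against ND, and 5 adjusted over the list alone (camera adjusted p = 0.0121, and adjusted p = 0.557 with an estimated correlation); the camera call was lost without ND replicate 4 or HFD replicate 1. Their list score was 0.00117 ± 0.295 in ND and 0.371 ± 0.303 in HFD (exact permutation p = 0.171). General hepatocyte markers in HFD against ND were negative in 9 of 12 members, with 1 down (median -0.13, camera adjusted p = 0.0879). Their list score was 0.000971 ± 0.0726 in ND and -0.156 ± 0.113 in HFD (exact permutation p = 0.0286).

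Male-biased liver genes were lower in HFD than in ND, with 6 of 15 down and 0 up, and 11 down adjusted over the list alone (median -0.87, camera adjusted p = 2.84e-08, and adjusted p = 0.275 with an estimated correlation); Cyp2f2 fell by 1.10 ± 0.15. Female-biased genes had 1 up and 3 down of 13 in HFD against ND, where the median was -0.47 and the mean 0.42. In HFD+MEC1 against HFD, male-biased genes were positive in 14 of 15 members, with 0 past the threshold and 1 higher adjusted over the list alone (median 0.26, camera adjusted p = 0.00471, and adjusted p = 0.54 with an estimated correlation), a camera call lost without HFD+MEC1 replicate 4. The male-biased list score was -0.956 ± 0.335 in HFD and -0.535 ± 0.501 in HFD+MEC1 (exact permutation p = 0.2). Of the 13 female-biased genes, 0 passed in HFD+MEC1 against HFD and 4 were lower adjusted over the list alone (median -1.01, camera adjusted p = 0.00065, and adjusted p = 0.353 with an estimated correlation). Their list score did not separate the groups, at -0.404 ± 0.290 in HFD and -0.540 ± 0.325 in HFD+MEC1 (exact permutation p = 0.543). Cyp3a16 and Cyp3a41b held at most 15 and 9 counts in these libraries. Cholangiocyte markers were negative in 10 of 10 members in HFD+MEC1 against ND, and 1 fell, over all genes or adjusted over the list alone (camera adjusted p = 0.00022, and adjusted p = 0.19 with an estimated correlation): Epcam, by 1.59 ± 0.35. Several of these markers held few counts, as given above. Clock genes in HFD+MEC1 against ND had 4 of 18 down and 0 up (camera adjusted p = 0.133); Per3 fell by 1.71 ± 0.41, and the time of sampling is not in the labels. The Per3 call was lost without ND replicate 2 or 4 or HFD+MEC1 replicate 3 or 4. Interferon response genes stayed above ND in HFD+MEC1, with 5 of 26 up and 0 down, and 9 up and 1 down adjusted over the list alone (camera adjusted p = 1.39e-06, and adjusted p = 0.19 with an estimated correlation); Usp18 rose by 1.12 ± 0.17. In the same comparison macrophage markers were positive in 17 of 18 members with 0 past the threshold, over all genes or adjusted over the list alone (camera adjusted p = 0.00022, and adjusted p = 0.334 with an estimated correlation). Sinusoidal endothelial markers were positive in 13 of 13, and 1 rose, over all genes or adjusted over the list alone (camera adjusted p = 0.000334, and adjusted p = 0.384 with an estimated correlation). Immediate early and heat shock genes had 4 of 19 up in HFD against ND (5 adjusted over the list alone), with Hspb1 up by 1.24 ± 0.16, and in HFD+MEC1 against HFD 4 were lower adjusted over the list alone, with Klf6 at -0.88 ± 0.16 (adjusted p = 0.0576). Of autophagy machinery genes 5 of 32 rose on HFD against ND (5 and 1 lower adjusted over the list alone), among them Ulk1 by 0.66 ± 0.16 and Atg14 by 0.56 ± 0.14, and of mitophagy genes 2 of 34 rose, Bcl2l13 by 0.33 ± 0.07 and Calcoco1 by 0.57 ± 0.13. The calls of Ulk1, Atg14 and Calcoco1 were lost without ND replicate 1 or 4 or HFD replicate 3, those of Ulk1 and Atg14 also without ND replicate 2 or HFD replicate 4.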
